A study of Homo sapiens with 54 samples.

How the data were processed

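The samples were 54 BrU-seq libraries from ZR751, T47D and MCF7 cells treated with 30 nM PF-9363 or DMSO for 4, 8 or 24 h, 3 libraries per group, grouped by the cell line, treatment and time in the labels. Per the labels' protocols, cells were labelled with 2 mM bromouridine for 30 min at the end of treatment, total RNA was extracted with Trizol, and isolation of labelled RNA, library preparation, sequencing and analysis followed a protocol cited from 2014. The genome build is hg38, per the submitters' processing notes. The aligner, the read counter, the annotation release, the use of strand and the test are not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Because the use of strand is not given, genes that overlap on opposite strands, antisense genes among them, are reported as uncertain, and likewise multicopy RNAs, pseudogenes and histone genes that share reads with near-identical copies.

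The deposited tables, 1 per line and time, hold 57733 genes each, and 57040 of the gene identifiers matched a reference list of gene names. Per the file headers each table gives the gene length, the RPKM of both groups, a normalised read signal of both groups, a log2 fold change, a shrunken log2 fold change, a p-value and an adjusted p-value. The RPKM values are group values made by the authors, and 3 times each is whole at the last decimal given (within 0.2 of a unit) for 100% of genes, as for means of 3. The deposited log2 fold change equals the log2 ratio of the groups' normalised signal to within 0.1 for 100% of expressed genes. The p-value columns hold the code 9 where the authors gave none, which was read as missing. No header names which group is treated: the direction, PF-9363 over DMSO, was taken from how the tables are named, and all directions rest on that. The table of ZR751 at 8 h carries a misspelt line name and was assigned by elimination. Its vehicle profile had Pearson's r of 0.995 and 0.981 with the other ZR751 tables over genes expressed in any table, where tables of different lines reached at most 0.735. Gene length equals the span from start to end for 96.6% of genes, so the deposited length covers introns. Start positions are counted from 0 in the tables: after adding 1, 7541 of 12924 genes whose end matched a reference annotation of the same genome also matched its start, against 138 without it. Coordinates are printed counted from 1.

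With group means only, no test between libraries could be run here, and the authors' own adjusted p under 0.05 was counted as a call, as had been set down for that case before the data were examined. Genes without an adjusted p in the authors' deposited table count as not tested. A protein-coding gene with an adjusted p and a mean RPKM of at least 0.5 over both groups counts as expressed. The standard error behind each fold change was recovered as the absolute log2 fold change over the normal quantile of its p-value. This was checked on the tables: the ratio of unshrunken to shrunken fold change, less 1, rose with the square of this standard error with Spearman's rho of 1.00 (rounded) across genes in every table. From it the 95% intervals were made. The difference between effects of different times or lines was tested as the difference of the log2 fold changes over the root of the summed squared standard errors, with Benjamini-Hochberg adjustment, for 6 pairs of tables. That test was chosen after the files were seen, since the joint model planned before needs values per library. Each table has its own vehicle group and its own scaling, so each fold change was formed within a table.

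Named genes followed a rule fixed before the data were examined: 8 index genes in every comparison, namely KAT6A, KAT6B, ESR1, MYC, GREB1, PGR, CCND1 and CDKN1A. To these were added the 6 largest falls and 6 largest rises among called genes with a mean RPKM of at least 0.5 at 24 h and 3 of each at 4 and 8 h, leaving out clone and locus names. Also taken were the members of each gene list with the smallest adjusted p, 2 per list and 4 where the list passed its own test, the genes called in one direction in all lines, ranked by the smallest of their 3 changes, and the 3 largest differences in each direction of each test of a difference. Gene lists were also fixed before, 21 in all: MYST acetyltransferases and their complex subunits, estrogen response, luminal transcription factors, luminal keratins and epithelial adhesion, G1/S and DNA replication, G2/M and mitosis, MYC and ribosome biogenesis, p53 targets, CDK inhibitors and pocket proteins, basal, stem and mesenchymal markers, HOX, MEIS and PBX genes, interferon response, unfolded protein and integrated stress response, immediate early genes, sterol and fatty acid synthesis, replication-dependent histones, other acetyltransferases with deacetylases and BET proteins, genes of the 8p11 region, housekeeping controls, and markers of leukocytes and of stroma, endothelium and fat. They named 675 symbols, older and current forms counted apart, of which 626 were in the tables. Each list's median log2 fold change was placed among 10000 random lists of protein-coding genes of the same size, matched on normalised reads in 20 bins, for 185 pairs of list and comparison with at least 2 tested members. 88 lay outside the central 95%, where 9.2 would if the genes of a list moved independently. The random lists hold genes drawn independently, and genes that move together between groups of libraries can fall outside more often. The 88 against 9.2 therefore does not measure how many lists the compound moved. A list's place among random lists does not change with a scale that shifts all genes alike. Overlaps were set against n1 x n2 / N per direction, with a two-sided Fisher exact test for pairs. That expectation treats every tested gene as equally likely to be called. Genes with more reads are called more easily in each table, and trends with gene length can run alike. An overlap above it therefore does not by itself measure a shared response.

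The difference test was tested on simulated data drawn with the real standard errors and 200 changed genes per pair of tables. For ZR751 24 h minus 4 h, over 21519 genes, it recovered 93% of differences of 1 (log2) and 69% of 0.5. For T47D 24 h minus 4 h, over 17186 genes, it recovered 55% and 3%, with 9.38% false calls. For T47D 24 h minus MCF7 24 h, over 19052 genes, 35% and 3% were recovered. The simulated noise came from the same standard errors that the test divides by, so a low rate of false calls was set in advance. It does not show whether those standard errors are right. Shifts of a whole table, in scale or with gene length, were not simulated. Changed genes were drawn from genes above a minimum of normalised reads, so recovery among scarcely read genes is not given. Of 100 random lists of 40 genes in T47D at 24 h, 5% lay outside the central 95%, and 94% lay below it after a shift of -0.2. They were drawn from the same genes as the lists they were compared with, so about 5% was fixed in advance. It does not show how lists of genes that move together behave. Alternatives were a 1.5-fold threshold and adjustment over every gene with a p, both planned, and, chosen after seeing the data, adjustment over genes with a mean RPKM of at least 0.5, a scale from the RPKM values in place of the authors' size factors, centring on the median of expressed protein-coding genes, subtraction of the running median over gene length in 20 bins, and random lists matched on RPKM or on level and length. The changes of scale and the length correction move a fold change and keep its standard error, so a call ends with them only because its fold change moved toward 0 or the adjusted threshold moved. Software was Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.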

Results

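Nascent transcription was measured in 54 libraries from 3 human breast cancer cell lines that express the estrogen receptor, ZR-75-1 (written ZR751), T47D and MCF7. Cells received 30 nM PF-9363, also called CTx-648, an inhibitor of the histone acetyltransferases KAT6A and KAT6B, or the vehicle DMSO, for 4, 8 or 24 h. Bromouridine at 2 mM was then given for 30 min and the labelled RNA was isolated and sequenced (BrU-seq), so the values follow RNA made during that pulse rather than the RNA pool of the cell. Each line and time had 3 treated and 3 vehicle libraries, 18 groups in all. The 9 tables used here, 1 for each line and time, give for 57733 genes a group mean in RPKM, reads scaled by gene length and library size, a group value of normalised reads, a log2 fold change of PF-9363 over DMSO and its p-value. The tables give no values of single libraries, so group means stand without SD. The precision of each fold change is given as the 95% interval implied by the deposited fold change and p-value, written after the log2 value.

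The depth of single libraries is unknown. The normalised reads of a group summed to between 45.5 M and 61.1 M, and the median expressed protein-coding gene held between 2292 and 2884 normalised reads. The precision differed more between comparisons than these group sums and medians, which do not show the depth of single libraries. The median standard error of a log2 fold change over expressed protein-coding genes was 0.0537 in ZR751 at 4 h and 0.061 at 24 h, against 0.217 in T47D and 0.194 in MCF7 at 24 h. A change that passes the threshold in ZR751 can therefore miss it in the 24 h tables of the other lines at the same size.

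The genes of the targeted enzymes came first. The authors' deposited tables gave KAT6A (ENSG00000083168.9, chromosome 8, 41929479 to 42051987, hg38) log2 fold changes between -0.26 and -0.03. It was called lower in MCF7 at 4 h alone, at -0.21 (-0.37 to -0.06), in the authors' deposited table, and that call was lost on the RPKM scale (-0.07) and after length correction (-0.04). KAT6B (ENSG00000156650.12, chromosome 10, 74825582 to 75032622) rose in T47D at 4 h, by 0.46 (0.25 to 0.67) with an adjusted p of 0.001 in the authors' deposited table. It was also called higher in ZR751 at 24 h in the authors' deposited table, by 0.13 (0.04 to 0.23), a call that ended after correction for gene length (0.10). KAT6B also passed as higher in T47D at 8 h on the RPKM scale (0.21) and after length correction (0.21), and in ZR751 at 4 h on the RPKM scale (0.10). Of the 19 MYST acetyltransferases and subunits of their complexes, 7 rose and 2 fell in ZR751 at 24 h, and the counts were the same adjusted over the list alone. Among them were JADE2, a subunit of KAT7 complexes, at 0.34 (0.24 to 0.45), and BRPF3, also a partner of KAT7, at 0.29 (0.18 to 0.39) in the authors' deposited table. The list median lay above the central 95% of 10000 random lists of matched level in ZR751 at 8 h (0.06), T47D at 4 h (0.13) and 8 h (0.10) and MCF7 at 8 h (0.02) and 24 h (0.06). With random lists matched on RPKM only the T47D calls held, and the percentile went from 97.9 to 96.2 in ZR751 at 8 h, from 97.6 to 85.8 in MCF7 at 8 h and from 98.7 to 91.3 in MCF7 at 24 h. After length correction and matching on level and length all these calls held, at 97.6 in ZR751 at 8 h and 99.7 and 99.9 in MCF7 at 8 and 24 h. MCF7 at 4 h then also lay above, at percentile 97.8.

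ESR1, which encodes estrogen receptor alpha, fell in all 9 comparisons. The gene (ENSG00000091831.23) spans chromosome 6, 151690496 to 152129619 of hg38, with 439 kb counted. In the authors' deposited tables its log2 fold change was -1.01 (-1.08 to -0.95) at 4 h, -0.85 (-0.98 to -0.72) at 8 h and -0.67 (-0.77 to -0.57) at 24 h in ZR751. The authors' deposited tables put T47D at -1.10 (-1.32 to -0.87), -1.17 (-1.29 to -1.04) and -1.19 (-1.63 to -0.74) at the same times. MCF7 stood at -0.85 (-0.99 to -0.71), -1.13 (-1.38 to -0.89) and -0.91 (-1.23 to -0.59) in the authors' deposited tables. At 24 h the group means in the authors' deposited tables were 1.35 against 2.16 RPKM in ZR751, 2.47 against 5.03 RPKM in T47D and 2.16 against 3.82 RPKM in MCF7, treated against vehicle. The adjusted p of ESR1 ran from 1.26e-184 in ZR751 at 4 h to 0.000103 in T47D at 24 h in the authors' deposited tables.

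**Figure D1:**
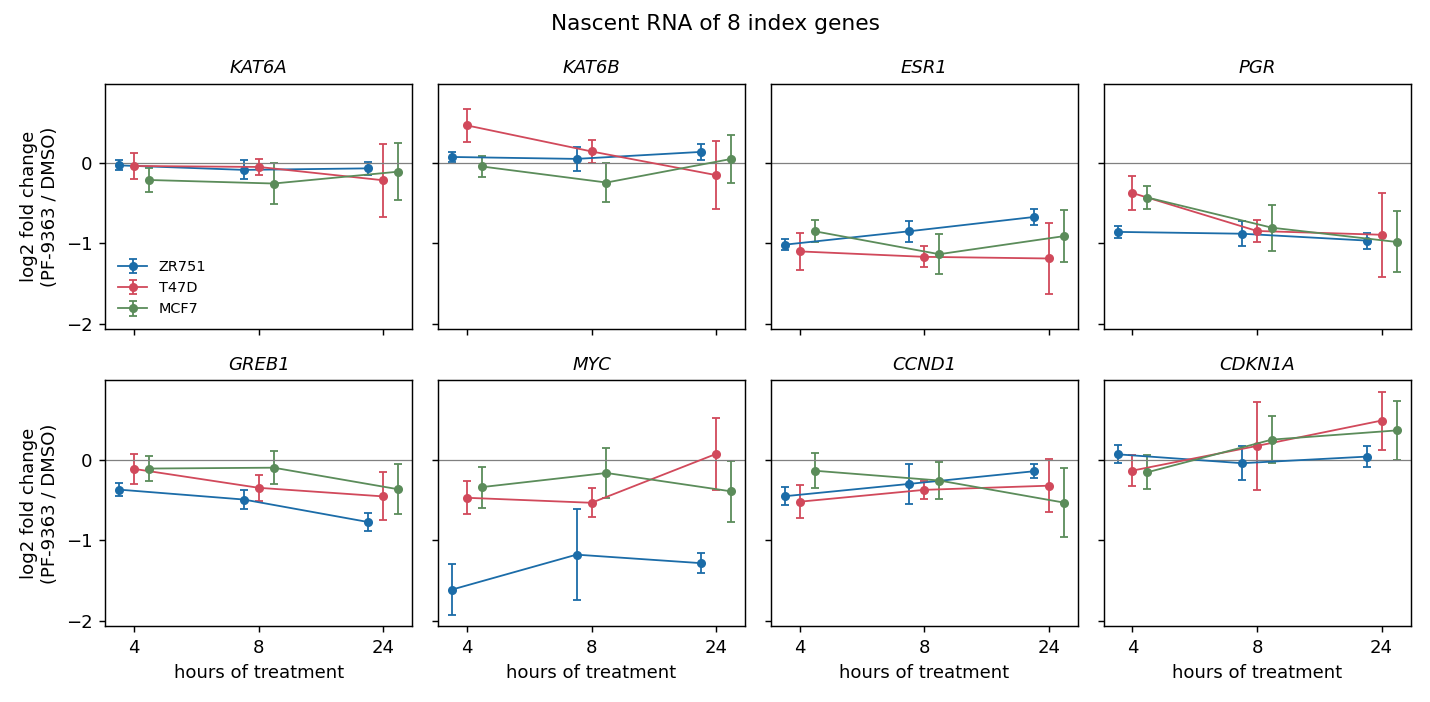
Log2 fold change of PF-9363 over DMSO (vertical axis) against hours of treatment (horizontal axis, 4, 8 and 24 h at equal spacing) for 8 genes fixed before the data were examined, 1 line per cell line. Points are the authors' deposited values and bars the 95% interval implied by their p-values; ESR1 lies between -1.19 and -0.67 in every comparison, and MYC lies below -1 in ZR751 alone.

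PGR, the progesterone receptor gene and a target of estrogen receptor, followed. In the authors' deposited tables it fell by 0.86 (log2) at 4 h in ZR751, by 0.37 in T47D and by 0.43 in MCF7. By 24 h the authors' deposited tables held -0.96 (-1.06 to -0.86) in ZR751 and -0.98 (-1.36 to -0.60) in MCF7. In T47D at 24 h PGR stood at -0.89 (-1.41 to -0.37) with an adjusted p of 0.0843 in the authors' deposited table, which did not pass. GREB1, another estrogen target, fell in ZR751 at each time, to -0.77 (-0.88 to -0.67) at 24 h, and in T47D at 8 h, to -0.35 (-0.51 to -0.19), in the authors' deposited tables. It passed at no time in MCF7, where the authors' deposited table gave -0.37 (-0.68 to -0.06) at 24 h. The difference at 24 h of ZR751 minus MCF7, -0.41 (SE 0.166), did not pass, with an adjusted p of 0.225 from the authors' values. That of T47D minus ZR751, 0.32 (SE 0.161), did not pass with the authors' scaling (adjusted p 0.403) but passed on the RPKM scale, at 0.51 with an adjusted p of 0.0441. MYC, which encodes a transcription factor of growth genes, fell in T47D at 4 h (-0.47, -0.68 to -0.27) and 8 h (-0.54, -0.72 to -0.35) and stood at 0.07 (-0.38 to 0.52) at 24 h in the authors' deposited tables. In MCF7 the MYC call at 4 h, at -0.34 (-0.60 to -0.09) in the authors' deposited table, was lost on the RPKM scale (-0.20), and MYC passed at neither later time. CCND1, which encodes cyclin D1, fell at 4 h in ZR751 (-0.45, -0.56 to -0.35) and T47D (-0.52, -0.73 to -0.32) and at 8 h in T47D (-0.38, -0.49 to -0.26) in the authors' deposited tables. Its call in ZR751 at 24 h, at -0.15 in the authors' deposited table, ended after correction for gene length (-0.10). CDKN1A, the gene of the cell cycle inhibitor p21, was called in none of the 9, with values between -0.16 and 0.48 in the authors' deposited tables. On the RPKM scale CDKN1A passed as higher in T47D at 24 h (0.66) and MCF7 at 8 h (0.43), and after length correction in ZR751 at 4 h (0.15).

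In ZR751 at 4 h most luminal transcription factor genes and most genes of ribosome biogenesis fell. The largest falls in the authors' deposited table were of MYC at -1.61 (-1.93 to -1.30), NR2F1, an orphan nuclear receptor gene, at -1.58 (-1.79 to -1.37), and EPOP, a partner of Polycomb and elongin, at -1.54 (-1.97 to -1.11). The largest rises at 4 h in the authors' deposited table were EGR1, an immediate early gene, at 1.20 (0.71 to 1.70), and the histone genes HIST1H4H and HIST1H4C, at 1.11 (0.37 to 1.85) and 1.11 (0.40 to 1.82). Of the 26 luminal transcription factor genes, 19 fell and 3 rose (19 lower and 4 higher adjusted over the list alone), with a median of -0.46, below all 10000 random lists. Of 39 genes of the list MYC and ribosome biogenesis, 37 fell and none rose (38 lower and 0 higher adjusted over the list alone), with a median of -0.47. The housekeeping controls were also lower there, in 10 of 18 cases with 1 higher (10 lower and 1 higher adjusted over the list alone), with a median of -0.17. Their place below random lists (percentile 0.54) ended with matching on RPKM (3.08) and after length correction and matching (6.86). The mitotic genes moved the other way: 28 of 42 rose and none fell (0 lower and 29 higher adjusted over the list alone), with a median of 0.18, above all random lists. In all, 6866 of 21949 tested genes were called at 4 h, 3789 lower and 3077 higher, and 1236 of them by at least 1.5-fold, where the majority turned, with 545 lower and 691 higher. The lower share of 55.2% became 42.6% with median centring and 44.8% after length correction.

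At 8 h in ZR751, 2461 of 17532 genes were called, 1323 lower and 1138 higher, and at 1.5-fold the majority turned, to 234 lower and 345 higher. HES7, a Notch pathway repressor gene, stood at -1.55 (-2.00 to -1.09), NR2F1 at -1.23 (-1.51 to -0.96) and SHOC2, a scaffold of RAS signalling, at -1.23 (-1.40 to -1.07) in the authors' deposited table. The authors' deposited table listed ALDH3B1 (0.97, 0.71 to 1.22), FLRT3 (0.82, 0.56 to 1.08) and FUT3 (0.82, 0.52 to 1.11) as the largest rises. MYC remained low, at -1.18 (-1.74 to -0.61) in the authors' deposited table, and 25 of 38 MYC and ribosome biogenesis genes were called lower and none higher (27 lower and 0 higher adjusted over the list alone), with a median of -0.37. Among 20 tested basal, stem and mesenchymal markers, 8 rose and none fell (0 lower and 10 higher adjusted over the list alone), with a median of 0.23 at percentile 99.9 of random lists. The share called lower was 53.8% with the authors' scaling, 30.0% on the RPKM scale and 43.7% after length correction.

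At 24 h the ZR751 profile included the genes of DNA replication. Of 50 G1/S and DNA replication genes 49 fell and none rose (50 lower and 0 higher adjusted over the list alone), with a median of -0.56, below all random lists. In the authors' deposited table the replication factor genes MCM10, MCM3, MCM6 and RFC3 stood at -0.90 (-1.03 to -0.77), -0.66 (-0.76 to -0.56), -0.69 (-0.79 to -0.58) and -0.59 (-0.69 to -0.50). The G2/M and mitosis list, raised at 4 h, was now lower: 28 of 42 fell and none rose (31 lower and 0 higher adjusted over the list alone), with a median of -0.18 and the checkpoint gene BUB1B at -0.33 (-0.42 to -0.24) and MAD2L1 at -0.46 (-0.60 to -0.33) in the authors' deposited table. MYC stayed at -1.28 (-1.41 to -1.16) in the authors' deposited table, and 32 of 39 MYC and ribosome biogenesis genes fell with none higher (34 lower and 1 higher adjusted over the list alone), among them DDX21 at -0.63 (-0.72 to -0.54) and URB2 at -0.67 (-0.76 to -0.57). Estrogen response genes fell in 33 of 49 cases and rose in 6 (median -0.29, below all random lists), and the count was 34 lower and 7 higher adjusted over the list alone. CA12 stood at -0.99 (-1.08 to -0.91) and RAB31 at -0.75 (-0.84 to -0.67), while BCAS1 rose by 0.70 (0.62 to 0.79), in the authors' deposited table.

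Other lists had medians above zero in ZR751 at 24 h. Of 32 interferon response genes 17 rose and none fell (0 lower and 18 higher adjusted over the list alone), with a median of 0.54, above all random lists. Their median level in the vehicle group was 0.0886 RPKM, under the 0.5 RPKM set for expressed genes. SAMD9, PARP14, DDX60 and PARP9 stood at 1.17 (0.96 to 1.39), 0.88 (0.72 to 1.03), 1.03 (0.80 to 1.25) and 0.77 (0.62 to 0.92) in the authors' deposited table. Among 33 immediate early genes 18 rose and 7 fell (7 lower and 19 higher adjusted over the list alone), with a median of 0.30, FOS at 1.29 (1.10 to 1.49), EGR1 at 1.19 (1.05 to 1.34) and NR4A1 at 0.98 (0.83 to 1.13) in the authors' deposited table. EGR3, of the same family, went against them at -1.31 (-1.66 to -0.95) in the authors' deposited table. The largest rises were the metallothionein gene MT2A at 1.32 (0.96 to 1.68), SAT1, which encodes an enzyme of polyamine breakdown, at 1.31 (1.17 to 1.45), FOS, the 7SL RNA gene RN7SL2 at 1.29 (0.81 to 1.76), MGP at 1.27 (1.03 to 1.51) and SMIM31 at 1.27 (1.14 to 1.39) in the authors' deposited table. RN7SL2 has many near-identical copies, so its reads are uncertain, and RNA of its class took 0.485% of the normalised reads in the treated group against 0.206% in the vehicle group. HES7, NR2F1, EGR3, MYC, KCNE4 and CKB had the largest falls, the last 2 at -1.27 (-1.49 to -1.04) and -1.26 (-1.54 to -0.99) in the authors' deposited table. Luminal transcription factor genes went both ways, 13 lower and 7 higher of 26 (13 lower and 7 higher adjusted over the list alone): TFAP2B fell by 0.90 and TFAP2A by 0.55 whereas EHF rose by 0.72 in the authors' deposited table. That list's place below random lists (percentile 0.02) ended after length correction and matching (percentile 8.26). The 24 h table held 7026 calls among 22414 genes, 3722 lower and 3304 higher, with 1716 of at least 1.5-fold. The majority turned at 1.5-fold, to 842 lower and 874 higher, with median centring, to 3262 lower and 3893 higher, and after length correction, to 3237 and 3826.

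In T47D at 4 h 13 of 25 luminal transcription factor genes were lower and none higher (17 lower and 0 higher adjusted over the list alone), with a median of -0.33, below all random lists. IRX5, a homeobox gene, had the largest fall at -1.76 (-1.94 to -1.58) in the authors' deposited table. CEBPB, a transcription factor gene, stood at -1.46 (-1.91 to -1.02) at 4 h and then rose at 8 h, by 0.80 (0.42 to 1.18), in the authors' deposited tables. Of 48 estrogen response genes 20 fell and 1 rose (24 lower and 1 higher adjusted over the list alone), with a median of -0.21. Immediate early genes were lower in 11 of 26 cases and higher in none (15 lower and 0 higher adjusted over the list alone), with a median of -0.32. Histone genes were lower in 5 of 38 cases and higher in none (7 lower and 0 higher adjusted over the list alone), with a median of -0.36. HOX, MEIS and PBX genes were lower in 6 of 22 (10 lower and 0 higher adjusted over the list alone), with a median of -0.28. The rises were smaller: the authors' deposited table gave ADSL 0.62 (0.26 to 0.98) and PGR-AS1, annotated beside PGR, 0.57 (0.35 to 0.80). The pseudogene HSPA8P3 (0.91) and the 7SL copy RN7SL4P (-1.47) were also called in the authors' deposited table, and both share reads with near-identical copies; the call of RN7SL4P ended after length correction (-1.38). In total 1037 of 17186 genes were called, 688 lower and 349 higher. The lower share was 66.3% and 44.6% on the RPKM scale.

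At 8 h in T47D, 36 of 48 estrogen response genes fell and 1 rose (39 lower and 1 higher adjusted over the list alone), with a median of -0.39, below all random lists. ESR1 led the falls, followed in the authors' deposited table by MAPT-IT1, a transcript within MAPT, at -1.16 (-1.43 to -0.90) and CYP1B1, an enzyme of estrogen metabolism, at -1.07 (-1.26 to -0.88). The counted span covers introns, so the reads of MAPT-IT1 and MAPT cannot be separated here. Interferon response genes rose in 16 of 34 cases and fell in none (0 lower and 19 higher adjusted over the list alone), with a median of 0.24 and OAS2 at 0.77 (0.63 to 0.91) in the authors' deposited table. INHBE rose by 0.72 (0.26 to 1.18) in the authors' deposited table. Of 42 mitotic genes 4 fell and none rose (7 lower and 0 higher adjusted over the list alone), with a median of -0.10 at percentile 0.04. The G1/S and the MYC and ribosome biogenesis medians, -0.04 and -0.06, lay at percentiles 2.41 and 1.24. Both places ended with matching on RPKM (4.78 and 2.79) and held after length correction and matching (0.07 and 0.13). Both medians turned positive on the RPKM scale (0.03 and 0.02). In total 1925 of 16820 genes were called, 1233 lower and 692 higher. The share lower, 64.1%, was 29.1% on the RPKM scale.

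At 24 h in T47D only 173 of 22345 genes passed, 144 lower and 29 higher, while 1727 had an unadjusted p under 0.05. Adjusted over genes with a mean RPKM of at least 0.5 the count was 58, 50 lower and 8 higher. Of the 141 genes lower over all tested genes that were also tested at 8 h, 129 had been called lower then, against 10.3 for independent sets. The largest falls in the authors' deposited table were BFSP2-AS1 at -1.75 (-2.07 to -1.43), STC1, which encodes the hormone stanniocalcin-1, at -1.51 (-1.97 to -1.04), the prostaglandin E synthase gene PTGES at -1.49 (-1.91 to -1.07), the estrogen-induced scaffold gene PDZK1 at -1.41 (-1.72 to -1.11), ESR1, and the polarity gene PARD6B at -1.13 (-1.59 to -0.68). SNCG (1.08, 0.48 to 1.67), GNMT (1.03, 0.54 to 1.52), MYCL (0.92, 0.52 to 1.32), CYR61 (0.85, 0.42 to 1.29), TP53INP2 (0.81, 0.45 to 1.17) and MCIDAS (0.81, 0.44 to 1.17) had the largest rises in the authors' deposited table. The calls of SNCG, GNMT and CYR61 ended after length correction, at 0.89, 0.80 and 0.63. Estrogen response genes fell in 8 of 50 cases over all genes and rose in none, with 30 lower and 1 higher adjusted over the list alone, and a median of -0.54, below all random lists; MAPT and CXCL12 stood at -0.97 (-1.30 to -0.63) and -0.87 (-1.18 to -0.56) in the authors' deposited table. No G1/S, mitotic or MYC and ribosome biogenesis gene passed the authors' adjusted threshold at 24 h in T47D, while 3, 0 and 2 of them had an unadjusted p under 0.05. The G1/S median of -0.09 lay below random lists matched on level (percentile 0.32), a place that ended with matching on RPKM (percentile 8.45) and held after length correction and matching (percentile 0.19). The RPKM scale, which leaves that place as it is, raised the median of expressed genes by 0.18 and turned the sign of the G1/S median (0.09). The histone list, lower at 4 h, had a median of 0.39 at 24 h, above all random lists, with no gene past the authors' adjusted threshold and 2 of 39 at an unadjusted p under 0.05. After length correction the histone median was 0.18, still above all random lists matched on level and length. The immediate early list, also lower at 4 h, had a median of 0.22 at percentile 99.9, with 1 of 31 genes higher and none lower (2 lower and 3 higher adjusted over the list alone). The share called lower, 83.2%, was 30.8% on that scale, 72.5% with median centring and 66.7% after length correction.

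In MCF7 at 4 h, 3629 of 16846 genes were called, 2402 lower and 1227 higher, and at 1.5-fold the majority turned, to 194 lower and 297 higher. The authors' deposited table placed the HMG-box gene BBX at -0.97 (-1.14 to -0.81), ESR1 at -0.85 and the zinc finger gene ZBTB10 at -0.85 (-1.05 to -0.65) as the largest falls. The calcium-binding protein gene S100A6 at 1.02 (0.53 to 1.52), the pseudogene RPSAP58 at 0.92 (0.47 to 1.36) and TOR2A at 0.84 (0.44 to 1.24) were the largest rises in the authors' deposited table. Of 25 luminal transcription factor genes 12 fell and 1 rose (16 lower and 1 higher adjusted over the list alone), with a median of -0.26 at percentile 0.13. Of 31 immediate early genes 9 fell and none rose (10 lower and 0 higher adjusted over the list alone), with a median of -0.28. CDK inhibitor and pocket protein genes fell in 5 of 8 cases (5 lower and 0 higher adjusted over the list alone), with a median of -0.25. Mitotic genes rose in 11 of 42 (0 lower and 11 higher adjusted over the list alone), with a median of 0.11, and interferon response genes in 11 of 26 (0 lower and 13 higher adjusted over the list alone), with a median of 0.35. The median level of these interferon response genes in the vehicle group was 0.196 RPKM, again under 0.5. Estrogen response genes were called lower in 18 and higher in 4 of 49 (20 lower and 5 higher adjusted over the list alone), and their median of -0.12, or 0.02 on the RPKM scale, was at percentile 52.2 of random lists. The RPKM scale raised the median of expressed genes by 0.14 and took the lower share from 66.2% to 20.2%, median centring to 43.8% and length correction to 37.4%.

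At 8 h in MCF7, 1441 of 16916 genes were called, 961 lower and 480 higher. In the authors' deposited table AGR3, an estrogen-regulated secretory gene, stood at -1.45 (-1.90 to -1.01), RAD17P1 at -1.23 (-1.63 to -0.82) and TMEM26 at -1.19 (-1.55 to -0.83). RAD17P1 (chromosome 7, 16864267 to 16866308) lies within the span of AGR3 (chromosome 7, 16859405 to 16881987), so the reads of the pair cannot be separated here. The keratin genes KRT16 and KRT81 rose by 1.25 (0.70 to 1.79) and 0.95 (0.54 to 1.37) and S100A6 by 1.11 (0.59 to 1.62) in the authors' deposited table. Luminal transcription factor genes fell in 10 of 25 cases and rose in 1 (12 lower and 2 higher adjusted over the list alone), with a median of -0.27 at percentile 1.38. Among the 49 estrogen response genes 13 were lower and 2 higher (16 lower and 3 higher adjusted over the list alone), with a median of -0.13, or 0.06 on the RPKM scale, at percentile 79.8 of random lists. That place depended on the matching: it was percentile 5.82 with matching on RPKM and 14.8 after length correction and matching. The RPKM scale raised the median of expressed genes by 0.18 and the share called lower was 10.9% on it against 66.7% with the authors' scaling, 44.3% with median centring and 30.1% after length correction.

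At 24 h in MCF7, the lists of estrogen response, DNA replication and histone genes had medians below all random lists, with a minority of each past the threshold. Of 50 estrogen response genes 17 fell and none rose (median -0.43, below all random lists), and the count was 27 lower and 1 higher adjusted over the list alone. RAB31, MYB, NPY1R and PDZK1 stood at -0.78 (-1.03 to -0.53), -0.96 (-1.29 to -0.63), -0.92 (-1.23 to -0.60) and -0.90 (-1.21 to -0.58) in the authors' deposited table. Of 50 G1/S and DNA replication genes 9 fell over all genes and 28 adjusted over the list alone, with none higher (median -0.41, below all random lists). The authors' deposited table gave CDC6 -1.01 (-1.31 to -0.71), GINS2 -0.98 (-1.31 to -0.64), CDC25A -0.97 (-1.31 to -0.64) and MCM10 -0.72 (-1.01 to -0.42). Histone genes fell in 11 of 42 cases (22 lower and 0 higher adjusted over the list alone), with a median of -0.59 and HIST1H4A at -1.40 (-2.04 to -0.75) and HIST1H3F at -1.09 (-1.56 to -0.62) in the authors' deposited table. The same list had a median of 0.16 at 4 h, at percentile 99.99. The immediate early list, lower at 4 h, had a median of 0.15 at 24 h, above all random lists matched on level, with 2 of 33 genes higher and none lower (1 lower and 4 higher adjusted over the list alone). The mitotic list, higher at 4 h, and the MYC and ribosome biogenesis list had medians of -0.22 and -0.16 at 24 h, at percentiles 0 and 0.02, with no gene past the authors' adjusted threshold and 3 and 6 at an unadjusted p under 0.05. On the RPKM scale these medians were -0.13 and -0.06. RAD17P1 (-1.73, -2.43 to -1.03), MYBL1 (-1.24, -1.70 to -0.78), the pseudogene UBE2FP1 (-1.23, -1.89 to -0.57), SFXN2 (-1.20, -1.52 to -0.87) and RMST (-1.19, -1.67 to -0.71) completed the largest falls in the authors' deposited table. KRT81, SLPI, QPRT, S100A9, FAM214B and RORC rose by 1.33, 1.26, 1.25, 1.07, 1.03 and 1.02 in the authors' deposited table. The CDK inhibitor gene CDKN2B rose by 0.75 (0.45 to 1.05), and by 0.99 (0.74 to 1.23) in ZR751, in the authors' deposited tables. In total 420 of 20737 genes passed, 259 lower and 161 higher, against 2222 at an unadjusted p under 0.05. Adjusted over genes with a mean RPKM of at least 0.5 the count was 160, 127 lower and 33 higher. The lower share of 61.7% was 34.8% on the RPKM scale and 51.2% after length correction.

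**Figure D2:**
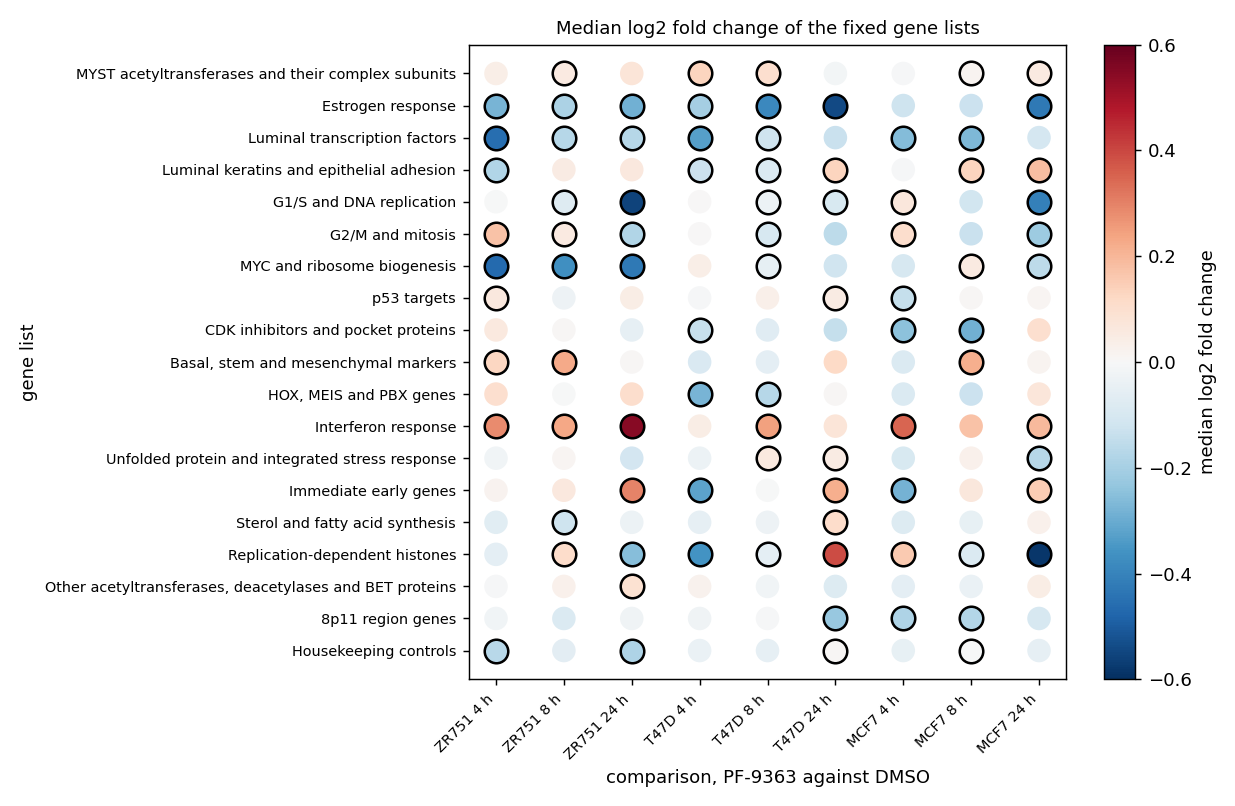
Median log2 fold change (color, authors' scaling) of gene lists (rows) in each of the 9 comparisons (columns). The marker lists of leukocytes and of stroma, endothelium and fat are not drawn. A black ring marks a median outside the central 95% of 10000 random lists of matched level. Of the 88 such medians, counted with the lists not drawn, 74 stayed outside on the same side with matching on RPKM. The estrogen response list is ringed in 7 comparisons and its medians run from -0.54 to -0.12; on the RPKM scale the MCF7 medians at 4 and 8 h, which are not ringed, turned positive (0.02 and 0.06).

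The 3 lines were then compared for genes called in the same direction. At 4 h, 237 genes were lower and 90 higher in all 3 lines, against 21.7 and 3.95 for independent sets. On the RPKM scale the balance turned, to 128 lower and 240 higher. ESR1, SIM2 and IRX5 had the largest shared falls at 4 h, with SIM2 at -1.25 in ZR751, -0.79 in T47D and -0.80 in MCF7 in the authors' deposited tables. IRX5 stood at -1.02, -1.76 and -0.79 in the same order in the authors' deposited tables. RAB7B, INPP5D and PSORS1C1 had the largest shared rises, though all 3 were scarcely transcribed, with RAB7B at most 0.125 RPKM in the vehicle groups of the authors' deposited tables. At 8 h, 206 were lower and 58 higher in all lines, against 5.34 and 1.03, led by ESR1, PRDM6 (-0.95, -0.84 and -0.82) and PGR among the falls and PRSS16, ACPP and PSORS1C1 among the rises of the authors' deposited tables. The balance at 8 h also turned, to 62 lower and 338 higher on the RPKM scale and 64 and 142 after length correction. At 24 h, 34 genes were lower in all 3 and 1 higher, against 0.277 and 0.0215. On the RPKM scale the counts at 24 h were 16 lower and 19 higher, and after length correction 21 and 7.

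The shared falls at 24 h were led by NXPH3, which stood at -1.87, -1.63 and -1.50 in ZR751, T47D and MCF7 in the authors' deposited tables. BMPER, a modulator of BMP signalling, stood at -1.53, -1.14 and -1.05, and RBM24 at -1.29, -1.03 and -1.05 in the authors' deposited tables. GFRA1, a GDNF family receptor, followed with -1.33, -0.97 and -1.14, then COL27A1 and MAPT-IT1, in the authors' deposited tables. The T47D call of COL27A1 ended on the RPKM scale (-0.80) and after length correction (-0.78), and that of MAPT-IT1 on the RPKM scale (-0.76). Because MAPT-IT1 lies within MAPT, its fall cannot be told from a fall of MAPT. Levels were low for several: in the authors' deposited tables GFRA1 had 7.5 RPKM in vehicle-treated MCF7 but 0.0792 in T47D and 0.0829 in ZR751. TP53INP2, an autophagy gene, was the single shared rise with the authors' scaling, at 0.89 (0.78 to 1.01), 0.81 (0.45 to 1.17) and 0.99 (0.61 to 1.37) in the authors' deposited tables. T47D and MCF7 shared 43 lower genes at 24 h against 1.56 for independent sets (two-sided Fisher exact test, p = 7.69e-51, Benjamini-Hochberg adjusted over 36 overlaps 1.07e-50). They shared 1 higher gene against 0.14 (exact p = 0.131), an overlap that did not pass. Genes are not independent replicates, so these tests describe the lists rather than new cultures. With a 1.5-fold threshold 18 of the 34 lower genes stayed, on the RPKM scale 16 and after length correction 20.

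Whether an effect at 24 h differed from that at 4 h was tested per gene as the difference of the deposited log2 fold changes. In ZR751 3013 of 21519 genes differed, 1406 more negative and 1607 more positive at 24 h, a majority that turned on the RPKM scale, with 1717 more negative and 1334 more positive. KCNH1, a potassium channel gene, went from 0.14 to -0.84 and MYBL2, a cell cycle transcription factor gene, from -0.06 to -0.94 in the authors' deposited tables. MGP, TP53INP1 and the proapoptotic gene BMF moved upward, TP53INP1 from -0.31 to 0.64 in the authors' deposited tables. ESR1 was less reduced at 24 h, by a difference of 0.34 (SE 0.0623), and GREB1 more reduced, with a difference of -0.40 (SE 0.0687). In T47D 50 of 17186 genes differed, 32 more negative and 18 more positive, against 89 on the RPKM scale, 22 more negative and 67 more positive. In MCF7 174 of 16808 differed. CDKN1A passed as more positive at 24 h in T47D on the RPKM scale alone (0.77). PDZK1 and PTGES became more negative in T47D, with differences of -1.30 (SE 0.174) and -1.18 (SE 0.234). CDKN2B and the integrin gene ITGB6 became more positive in MCF7, by 1.22 (SE 0.203) and 1.15 (SE 0.219), CDKN2B from -0.47 to 0.75 in the authors' deposited tables.

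Lines were compared at 24 h in the same way. T47D and ZR751 differed for 448 of 20354 genes, ZR751 and MCF7 for 461 of 19084, and T47D and MCF7 for 22 of 19052. The count for T47D minus ZR751 rose to 893 on the RPKM scale, and its direction went from 249 more negative and 199 more positive to 139 and 754, and to 215 and 250 after length correction. For ZR751 minus MCF7 it went from 210 and 251 to 359 and 184 on the RPKM scale, and to 268 and 246 after length correction. CDKN1A passed for T47D minus ZR751 on the RPKM scale alone (0.63). With the authors' scaling, of the 6611 genes called in ZR751 and not in T47D, 387 passed the test of the difference. MYC was among them: it stood at 0.07 in T47D and -1.28 in ZR751 in the authors' deposited tables, a difference of 1.35 (SE 0.238). For MYC the difference of ZR751 minus MCF7 was -0.89 (SE 0.204). The effect on ESR1 did not pass as different between any pair of lines at 24 h, with a difference of -0.51 (SE 0.233) for T47D minus ZR751 and 0.24 (SE 0.171) for ZR751 minus MCF7. The homeobox gene HOXC6 fell in ZR751 at 24 h, by 1.11, and stood at 0.27 in MCF7 in the authors' deposited tables, a difference of -1.38 (SE 0.274). HIST1H4C rose in ZR751 (1.09) and fell in MCF7 (-1.11) in the authors' deposited tables, with a difference of 2.21 (SE 0.358). It did not stand for the histone list, which was lower at 24 h in both lines. In ZR751 14 of 37 histone genes fell and 6 rose (17 lower and 6 higher adjusted over the list alone). The list median there was -0.25, below all random lists, against -0.59 in MCF7. AMIGO2 fell in ZR751 (-1.14) and stood at 0.29 in T47D in the authors' deposited tables, a difference of 1.42 (SE 0.283). STC1 was lower in T47D than in MCF7 by a difference of -1.15 (SE 0.284), which did not pass on the RPKM scale (-1.06).

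Fold changes followed gene length in most comparisons. Over expressed protein-coding genes Spearman's rho between log2 fold change and gene length was 0.22, -0.229 and 0.166 in ZR751 at 4, 8 and 24 h, 0.0551, -0.221 and -0.522 in T47D, and -0.336, -0.506 and -0.262 in MCF7. These are correlations across genes, which are not independent replicates. ESR1 is a long gene, and its fold changes after length correction stayed between -1.09 and -0.65, past the threshold in all 9 comparisons.

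**Figure D3:**
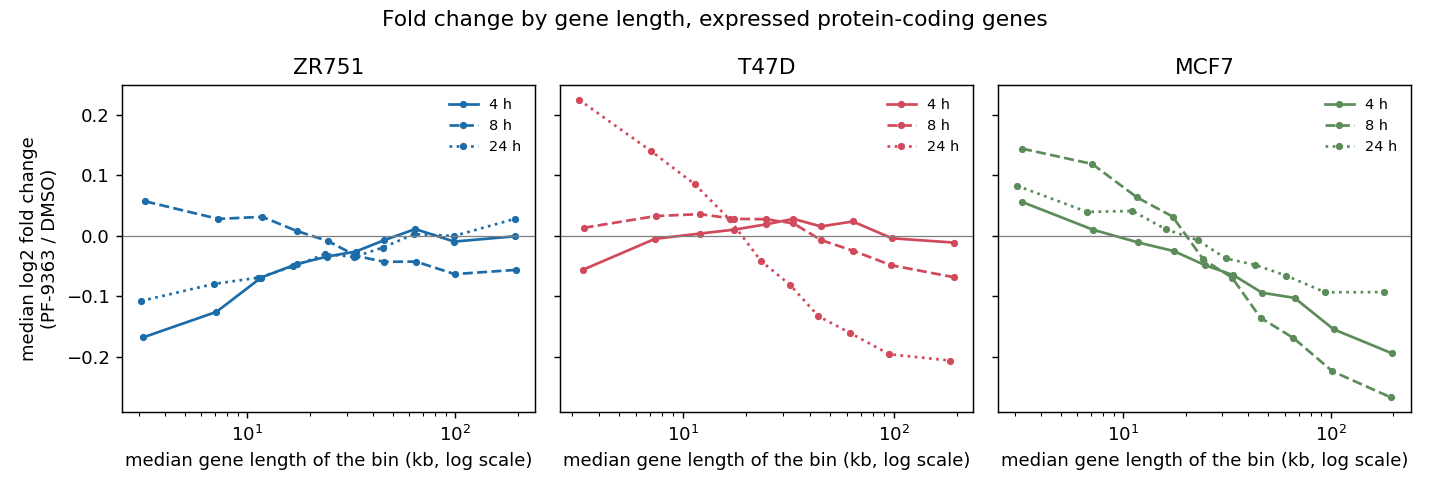
Median log2 fold change (vertical axis, authors' scaling) of expressed protein-coding genes in 10 bins of equal size by gene length (horizontal axis, kb, log scale), 1 panel per line and 1 curve per time. In T47D at 24 h the median runs from 0.23 in the shortest bin to -0.21 in the longest, and in MCF7 at 8 h from 0.14 to -0.27.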

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

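The tests of differences between times and lines were chosen after the files were seen, as were the tests of fold change size; the tests that set ZR751 fold changes against other lines' standard errors were written down before their result was seen. Each result here was picked out because the effect of PF-9363 differed between times of a line or between lines, by the test of the difference at an adjusted p under 0.05. Signs give the first named effect minus the second, in log2 units.

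Between 24 h and 4 h, 3013 genes differed in ZR751, 50 in T47D and 174 in MCF7. In ZR751 the differences were -0.99 for KCNH1, -0.88 for MYBL2 and -0.87 for U1, an annotated copy of a multicopy small RNA gene. On the positive side stood MGP (0.98), TP53INP1 (0.95) and BMF (0.91). The index genes ESR1 (0.34), GREB1 (-0.40) and CCND1 (0.31) also differed. In T47D the differences were -1.81 for BFSP2-AS1, -1.30 for PDZK1 and -1.18 for PTGES. RN7SL5P (2.31), CEBPB (1.58) and STK24-AS1 (1.35) were positive in T47D. After length correction all 3 no longer passed but stayed positive, at 1.97 (adjusted p 0.0905), 1.23 (0.136) and 1.01 (0.175), so the lost calls do not show that the length trend explains them. In MCF7 HIST1H4A (-1.47), HIST1H2BO (-1.41) and RAD17P1 (-1.40) were more negative at 24 h and KRT81 (1.31), CDKN2B (1.22) and ITGB6 (1.15) more positive.

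Between lines at 24 h, 448 genes differed for T47D minus ZR751, 22 for T47D minus MCF7 and 461 for ZR751 minus MCF7. For T47D minus ZR751 the lowest named differences were RN7SL2 (-1.31), MGP (-1.19) and MPP7 (-1.12), and the highest were CKB (1.62), COMTD1 (1.44) and AMIGO2 (1.42), with MYC at 1.35. MPP7 and COMTD1 no longer passed after length correction, at -0.87 (adjusted p 0.0596) and 1.06 (0.0788), values that kept their sign and most of their size. STC1 (-1.15) was the one gene of T47D minus MCF7 that met the naming rule. For ZR751 minus MCF7 the values were -1.59 for FAM173A, -1.44 for EGR3, -1.38 for HOXC6, -0.89 for MYC, 2.21 for HIST1H4C, 1.98 for HIST1H4A and 1.87 for MT2A.

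Far fewer genes were called at 24 h in T47D (173) and MCF7 (420) than in ZR751 (7026). Larger spread between libraries could account for this alone only if ZR751 fold changes set against the other lines' standard errors gave about as few calls. They gave 869 with the T47D errors, where 162 of the genes tested in both were called, and 1326 with the MCF7 errors, where 375 were called, which argues against spread as the whole cause, although it took the ZR751 count down from 6726 and 6691. Over genes called in ZR751 the median change in the ZR751 direction was 0.231 of the ZR751 median in T47D (bootstrap 95% interval over genes 0.205 to 0.256) and 0.349 in MCF7 (0.326 to 0.371), as smaller effects in these lines would give. The genes were chosen by their ZR751 call, which enlarges the ZR751 side of that ratio. The ratio would also be low if partly different genes responded in each line, and genes chosen by T47D or MCF7 calls were not examined. With the authors' scaling not every list was less changed there at 24 h: estrogen response medians were -0.54 in T47D and -0.43 in MCF7 against -0.29 in ZR751. On the RPKM scale they were close, at -0.36 and -0.34 against -0.30, and after length correction -0.48 and -0.39 against -0.26. The difference between lines was not tested for lists. G1/S medians with the authors' scaling went the other way, at -0.09 and -0.41 against -0.56. Why the ratio was low stays open: neither a weaker treatment of these cultures nor a property of the lines was tested.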

How the results depend on the processing

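The 1.5-fold threshold, adjustment over every gene with a p, and the 1.5-fold overlaps were planned; all other alternatives were chosen after seeing the data. No paired analysis was possible because the tables hold group means only. For the same reason the planned size factors, pseudocounts, count tests, joint fits of 18 libraries, list tests with an estimated correlation, runs without single libraries and counts over other splits of the libraries were not run, so how far 1 library carries a call is unknown. At least 1.5-fold left 1236 in ZR751 4 h, 579 in ZR751 8 h, 1716 in ZR751 24 h, 229 in T47D 4 h, 279 in T47D 8 h, 491 in MCF7 4 h, 584 in MCF7 8 h. Adjustment over every gene with a p gave 689 in T47D 4 h, 935 in MCF7 8 h. Adjustment over genes with a mean RPKM of at least 0.5, which tests fewer genes, gave 4391 in ZR751 4 h, 1158 in ZR751 8 h, 4326 in ZR751 24 h, 521 in T47D 4 h, 1036 in T47D 8 h, 58 in T47D 24 h, 2229 in MCF7 4 h, 726 in MCF7 8 h, 160 in MCF7 24 h. The RPKM scale gave 266 in T47D 24 h, 2957 in MCF7 8 h, and the other 7 counts stayed within 1.5 times, as did all 9 with median centring and with length correction. Counts of like size did not always hold the same genes. With length correction 693 of the 1441 calls of MCF7 8 h were kept in the same direction, and 2396 of 3629 in MCF7 4 h. On the RPKM scale 2100 of those 3629 were kept, against 6918 of 7026 in ZR751 24 h. That scale moved the differences to 89 genes for T47D 24 h minus 4 h and 893 for T47D minus ZR751. The other 4 differences stayed within 1.5 times on this scale and all 6 with length correction. Of the 50 genes of T47D 24 h minus 4 h, 20 were kept with length correction. Genes shared by the 3 lines at 1.5-fold numbered 15 lower and 3 higher at 4 h, 13 and 6 at 8 h and 18 lower at 24 h. On the RPKM scale they were 128 and 240 at 4 h, 62 and 338 at 8 h, and 16 and 19 at 24 h. With length correction they were 64 and 142 at 8 h and 21 and 7 at 24 h. The cause of these moves was not tested. Of gene lists, 79 lay outside the central 95% with matching on RPKM, 74 of them on the same side as in the 88 of the report, and 91 with length correction, 75 of them on the same side. With length correction the histone list in ZR751 at 4 h turned from percentile 32.9 to 99.5 and the luminal transcription factor list in T47D at 24 h from 55.3 to 1.36, both inside the central 95% before; the cause was not tested. On the RPKM scale and with length correction together, named genes kept their call or lack of call in 505 of 524 cases, lost it in 13 and gained it in 6, and no call turned sign. Differences of single genes were kept in 149 of 158 cases, lost in 6 and gained in 3. With matching on RPKM and, apart from it, with length correction and matching on level and length, single lists kept their place in 322 of 370 cases, lost it in 27, gained it in 19 and turned in the 2 named above.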

Other observations

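The split of HOX genes by cluster, the test on the sign of the trend with gene length and the test of timing of the estrogen response were chosen after results were seen; the tests of vehicle groups, of length and of scale were written down before. The HOX genes did not move as 1 group, which the list median hid. In ZR751 at 4 h, 7 of 9 tested HOXC genes fell and none rose, with a median log2 fold change of -1.24, and at 24 h 5 of 9 fell (median -1.02). The scarcely transcribed HOXB genes had medians of 0.42 at 4 h and 0.52 at 24 h, with 2 of 5 higher at 24 h. In T47D at 4 h 4 of 9 HOXC genes fell (median -0.33), and in MCF7 at 4 h 1 of 5 (median -0.34). At 24 h the HOXC medians were -0.23 over 9 genes in T47D and 0.06 over 6 in MCF7, and the difference between lines was not tested for the cluster. HOXC4 (chromosome 12, 54035362 to 54056030) stood at -1.03 (-1.14 to -0.93) in ZR751 at 24 h and MEIS2, a partner of HOX proteins, rose there by 0.94 (0.82 to 1.07) in the authors' deposited table. SHOC2, named at 8 h in ZR751, stood between -1.23 and -1.15 at its 3 times in ZR751, between -0.86 and -0.65 in T47D and between -0.60 and -0.41 in MCF7 in the authors' deposited tables, and passed in all but the 24 h tables of T47D and MCF7.

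Housekeeping genes fell in 10 of 18 cases and rose in 1 in ZR751 at 4 h (10 lower and 1 higher adjusted over the list alone), with a median of -0.17 at percentile 0.54, or -0.08 and percentile 6.86 after length correction and matching. They fell in 11 of 18 cases and rose in 1 in ZR751 at 24 h (median -0.19, and -0.19 on the RPKM scale), with RPLP0 at -0.52 and GAPDH at -0.38 in the authors' deposited table, and passed the authors' adjusted threshold in none of 18 in T47D or MCF7 at 24 h, where 1 and 3 had an unadjusted p under 0.05. At ZR751 24 h p53 target genes split, 6 lower and 9 higher of 29, and unfolded protein and integrated stress response genes too, 8 and 4 of 28, with ATF3 at 0.57 in the authors' deposited table. Sterol and fatty acid synthesis genes there were 9 lower and 4 higher of 29, and other acetyltransferase, deacetylase and BET genes 3 and 9 of 24. Luminal keratin and adhesion genes fell in 10 of 20 cases in ZR751 at 4 h (median -0.18, percentile 0.77, or 4.46 after length correction) and had a median of 0.19 in MCF7 at 24 h. Genes of the 8p11 region, which holds KAT6A, fell in 8 of 24 cases in MCF7 at 4 h (median -0.19, and -0.04 on the RPKM scale), and their median in T47D at 24 h, where none passed and 3 had an unadjusted p under 0.05, was -0.23 at percentile 0.36, or -0.05 on the RPKM scale and -0.10 after length correction. In ZR751 at 4 h 10 of 25 fell and 1 rose (10 lower and 2 higher adjusted over the list alone), with a median of -0.02, inside the random range at percentile 44.9, whose sign turned on the RPKM scale (0.01) and after length correction (0.01). Of the leukocyte markers at most 4 were tested in any comparison and at most 1 passed, and of the markers of stroma, endothelium and fat at most 10 were tested and 2 passed. The median of the latter in ZR751 at 24 h was -0.59 over 10 scarcely transcribed genes (median 0.0336 RPKM in the vehicle group), below random lists at percentile 0.07, with 1 gene higher and none lower (0 lower and 1 higher adjusted over the list alone). The leukocyte gene PTPRC had 0.000967 RPKM and the fat cell gene PLIN1 0.742 RPKM in vehicle-treated ZR751 at 24 h in the authors' deposited table.

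Fold changes followed gene length, with rho from -0.522 to 0.22 across the 9 tables. A single effect of the compound on long genes in every line and time is argued against by the sign, since 6 tables had a negative rho and 3 a positive one. Differences between sets of libraries that arise without the compound are a candidate explanation: the vehicle means of different times of a line differed with gene length, at an absolute rho of at least 0.2, in 6 of 9 pairs, with rho from -0.51 to 0.401. Time in culture differs between those vehicle groups as well, so part of that trend may be biological, and a length-dependent effect of the compound in some lines or times stays open.

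The estrogen response list had a median below all random lists at 24 h in each of the 3 lines. After length correction the highest of the 3 list medians was -0.26, with each below all random lists matched on level and length, and on the RPKM scale it was -0.30, which argues against the length trend and the scale as the whole cause. A hypothesis is that loss of ESR1 transcription comes first and other estrogen response genes follow. At 4 h the list already lay below all random lists in ZR751, with 28 lower and 4 higher of 49. It did so too in T47D, with 20 lower and 1 higher of 48, but not in MCF7 (percentile 52.2). ESR1 was already at -1.01, -1.10 and -0.85 at 4 h in ZR751, T47D and MCF7 in the authors' deposited tables, while the median paired change of the list without ESR1 from 4 h to 24 h was -0.10, -0.34 and -0.33, with 29 of 48, 38 of 47 and 40 of 48 genes lower at 24 h. The 8 h values do not show that order in every line: the list medians at 4, 8 and 24 h were -0.26, -0.18 and -0.27 in ZR751, -0.20, -0.38 and -0.53 in T47D, and -0.12, -0.12 and -0.43 in MCF7. By these medians the list was no lower at 8 h than at 4 h in ZR751 and MCF7. After length correction the MCF7 median, ESR1 included, was -0.02 at 4 h and -0.06 at 8 h. In ZR751 ESR1 itself was less reduced at 24 h than at 4 h, by 0.34. The order therefore stays open, and a separate, slower action of the compound on the same genes was not tested.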
